A study of Mus musculus with 12 samples.

How the data were processed

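RNA was profiled in cells from E7.5 mouse embryos that carry a Foxf1::venus knock-in, in which the fluorescent protein VENUS reports expression of Foxf1, on a C57BL/6 background. Per the labels' protocols, dissociated embryos were stained with antibodies, and 50 cells per sample were sorted by fluorescence-activated cell sorting directly into the lysis buffer of the SuperAmp kit, which is made for very small cell numbers. The RNA was turned into biotinylated sense-strand DNA with a whole-transcript labelling assay and hybridised to Affymetrix mouse exon arrays. The design text describes 3 sorted populations with 2 biological replicates each, which the sample titles call sort 1 and sort 2. The 12 deposited samples are the same 6 arrays summarised by gene and by exon-level probe set, and they were counted here as 6 samples. Which embryos went into a sort is not given in the sources used here.

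The deposited values of both tables are signals on the log2 scale, for which the submitters' processing notes name Affymetrix Power Tools and RMA (robust multi-array average) without versions. The gene table holds 22400 rows with Ensembl gene IDs and the exon-level one has 128950 rows with probe set numbers. The log2 scale was read from the values, which ran from 3.11 to 14.17 in the gene table with array medians between 6.00 and 6.07. How probe sets were grouped into genes is not given in the sources used here. Of the gene-level values, 60.9% equalled an exon-level value of the same array to 6 decimals, against 15.1% for another array, and 6439 gene rows (28.7%) equalled a single probe set on all 6 arrays. No detection calls were used here, so a low signal cannot be called absent, and differences from a population near the bottom of the scale are those of the deposited values only. RMA summaries tend to compress large differences. For arrays, the number of arrays limits the precision: the median standard error of a difference between populations was 0.25 log2 units.

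The deposited log2 values were used as they stand. Each gene was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes without trend or robust prior) over all 6 arrays with population as the only factor, giving 3 residual and 4.27 prior degrees of freedom. The 3 contrasts between populations were tested two-sided, with Benjamini-Hochberg adjustment over all 22400 rows within each contrast, at an adjusted p under 0.05. All adjusted p-values in the text come from limma. This design, the threshold and the main alternatives were fixed before the data were examined. Principal components and Pearson correlations across genes described how close the arrays were. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. The fit was tested on 20 simulated data sets of 22400 genes for the comparison of the FLK1-positive populations, each with 200 changed genes of mixed sizes. It recovered 3.4% of changes of 1 log2 unit, 75.4% of those of 2 units, 94.6% of those of 3 units and 98.5% of those of 4 units, while 5.03% of its calls were false.

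The files do not pair the gene IDs with names. The reference table used here holds 49997 genes of assembly GRCm38.p6 but no Ensembl IDs, and 0 of the 22400 IDs matched, so genes are given by ID and no position is given. The planned tests that need gene names were therefore not run. These are the tests of 28 gene lists fixed beforehand, the check of the sorting genes Foxf1 and Kdr (which encodes FLK1), and the averaging of probe sets per gene. The labels of the populations are used as given, with a doubt about the double-positive label stated beside the values of ENSMUSG00000042812. The planned rule for named genes took the largest log2 differences per direction among genes past the threshold whose arrays did not overlap, filled up where too few passed by the smallest p among genes differing by at least 1 log2 unit. It was kept for the order of the genes, but shortened to 2 IDs per direction and comparison because the IDs carry no names.

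The alternatives were quantile normalization again, median centring, leaving out the dimmer 50% of rows, an intensity trend with a robust prior, array weights, fitting only the populations compared, the sort number as a block, a minimum difference of 1 log2 unit, and leaving out each array in turn. Testing the exon-level probe sets ungrouped and leaving out gene rows equal to a single probe set were added after the data had been seen. The analyses of the position of the double-positive cells, of genes shared between comparisons, of genes private to a population, of covariance between separate arrays and of mixing between populations were also chosen after the data had been seen.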

Results

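The transcriptomes of 3 cell populations from E7.5 mouse embryos were compared. The embryos carried the fluorescent reporter VENUS at Foxf1, a gene for a forkhead transcription factor of the mesoderm. The cells were sorted by VENUS and by FLK1, the vascular endothelial growth factor receptor found on mesodermal precursors of blood and endothelium. The populations were FLK1-positive FOXF1-negative cells, FLK1-positive FOXF1-positive cells (called double-positive here) and FLK1-negative FOXF1-positive cells. Each was measured on 2 arrays from 2 sorts of 50 cells, and expression was given as a log2 signal for 22400 genes. The array medians lay between 6.00 and 6.07, and the median standard deviation between the 2 sorts of a population was 0.182 to 0.189 log2 units. The genes carry Ensembl IDs without names, so cell types and pathways were not assigned, and whether the signals of the sorting genes match the labels of the populations was not checked here. The populations are therefore named as labelled, and for the double-positive cells the label is in doubt if ENSMUSG00000042812, described with its values under the comparison by FLK1, is Foxf1.

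The FLK1-negative FOXF1-positive cells stood apart from both FLK1-positive populations, and the double-positive cells lay between the others on the first principal component. On that component, which held 30.0% of the variance, the FLK1-positive FOXF1-negative arrays scored -23.1 and -32.8. The double-positive arrays scored -9.39 and -7.14, and the FLK1-negative FOXF1-positive arrays 30.6 and 41.8. The second component held 21.8% and had a higher score for sort 1 than for sort 2 in all 3 populations. Across genes, which are not independent replicates, arrays of the double-positive and FLK1-positive FOXF1-negative cells correlated with a mean r of 0.957. The mean r was 0.951 between the FOXF1-positive populations and 0.945 between the FLK1-negative FOXF1-positive and FLK1-positive FOXF1-negative cells. The 2 sorts of a population correlated with r between 0.957 and 0.959. Between the FLK1-positive populations, r was 0.964 for the sort 1 arrays, above that range. It was 0.956 for the sort 2 arrays, and 0.956 and 0.9535 for arrays of unlike sort number, all below that range. The mean of 0.957 thus rests partly on 1 pair of arrays with the same sort number.

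**Figure D1:**
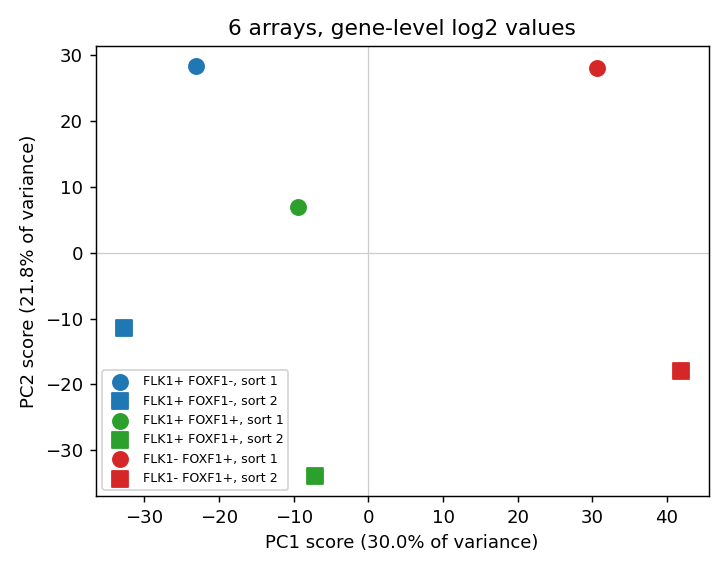
Scores of the 6 arrays on the first and second principal components of the gene-level log2 values, coloured by population, with circles for sort 1 and squares for sort 2. The double-positive arrays score -9.39 and -7.14 on the first component, between the FLK1-positive FOXF1-negative arrays (-23.1 and -32.8) and the FLK1-negative FOXF1-positive arrays (30.6 and 41.8).

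The comparison of double-positive with FLK1-positive FOXF1-negative cells sets FLK1-positive cells sorted as VENUS-positive against those sorted as VENUS-negative. No gene passed the threshold in limma in either direction, and the smallest adjusted p was 0.135. The gene with that p, ENSMUSG00000052217, had a log2 signal of 3.65 ± 0.06 (SD, n = 2) in double-positive and 6.89 ± 0.54 in FLK1-positive FOXF1-negative cells. For ENSMUSG00000039720 the signals were 5.13 ± 0.19 and 7.20 ± 0.19 (adjusted p = 0.163). Among genes higher by at least 1 log2 unit in double-positive cells, the smallest p-values were those of ENSMUSG00000070473, at 8.75 ± 0.19 against 6.55 ± 0.05 (adjusted p = 0.141), and ENSMUSG00000054850, at 8.05 ± 0.28 against 6.26 ± 0.07 (adjusted p = 0.230). The signal of ENSMUSG00000054850 equalled that of 1 probe set. At an unadjusted p under 0.05 there were 1047 genes, or 4.67%, where chance gives 5%, and 1272 genes with the sort number as a block. At an unadjusted p under 0.001 there were 54, where chance gives 22.4. On simulated data with 200 changed genes, the test recovered 75.4% of changes of 2 log2 units but 3.4% of changes of 1 log2 unit. With fewer changed genes the adjusted threshold is stricter, so these shares can overstate the recovery here. ENSMUSG00000052217 did not pass at a difference of -3.24 log2 units. The absence of calls thus excludes neither small differences nor differences of 2 log2 units or more in some genes.

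The comparison of double-positive with FLK1-negative FOXF1-positive cells asks what goes with FLK1 among cells sorted as VENUS-positive. Here 64 genes passed the threshold, 49 higher and 15 lower in double-positive cells. The 49 genes were higher by a median of 2.80 log2 units (range 1.57 to 6.97), and the 15 genes had a median difference of -2.29 (range -3.79 to -1.68). The largest difference was that of ENSMUSG00000041378, with a log2 signal of 10.55 ± 0.25 (SD, n = 2) in double-positive and 3.58 ± 0.02 in FLK1-negative FOXF1-positive cells, a difference of 6.97 ± 0.22 (SE, adjusted p = 0.000109). ENSMUSG00000093467 followed at 10.16 ± 0.21 against 4.80 ± 0.77 (adjusted p = 0.00421). In the other direction, ENSMUSG00000035783 was at 7.57 ± 0.28 in double-positive and 11.37 ± 0.11 in FLK1-negative FOXF1-positive cells (adjusted p = 0.0108). ENSMUSG00000042812 was at 4.58 ± 0.32 against 8.21 ± 0.43 (adjusted p = 0.00751), and at 4.57 ± 0.20 in FLK1-positive FOXF1-negative cells. The files do not settle whether ENSMUSG00000042812 is the sorting gene Foxf1. If it is, these signals go against the double-positive label, since they differed by 0.01 ± 0.29 log2 units (SE, adjusted p = 0.9999) between double-positive and FLK1-positive FOXF1-negative cells. The sort read the VENUS protein and the array reads RNA, so the signals alone do not decide whether the label holds. The signals of ENSMUSG00000041378, ENSMUSG00000093467 and ENSMUSG00000042812 each equalled that of 1 probe set. At an unadjusted p under 0.05 there were 1313 genes, or 5.86%. The mean of the FLK1-positive FOXF1-negative cells, whose arrays entered these calls only through the pooled spread, lay nearer to the double-positive than to the FLK1-negative FOXF1-positive mean for 47 of the 49 genes and 14 of the 15. The counts fell when any 1 array was left out, also a FLK1-positive FOXF1-negative array, which is not part of this contrast. Each such fit has fewer residual degrees of freedom. The fall was larger for an array of the populations compared, which left 1 array in its population. The fall therefore does not show whether particular arrays carried the calls. Without double-positive sort 1 or sort 2, the adjusted p was 0.0670 or 0.0546 for ENSMUSG00000093467, 0.158 or 0.0957 for ENSMUSG00000035783 and 0.0911 or 0.0546 for ENSMUSG00000042812, and for ENSMUSG00000035783 it was 0.0864 or 0.0744 without FLK1-negative FOXF1-positive sort 1 or sort 2.

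**Figure D2:**
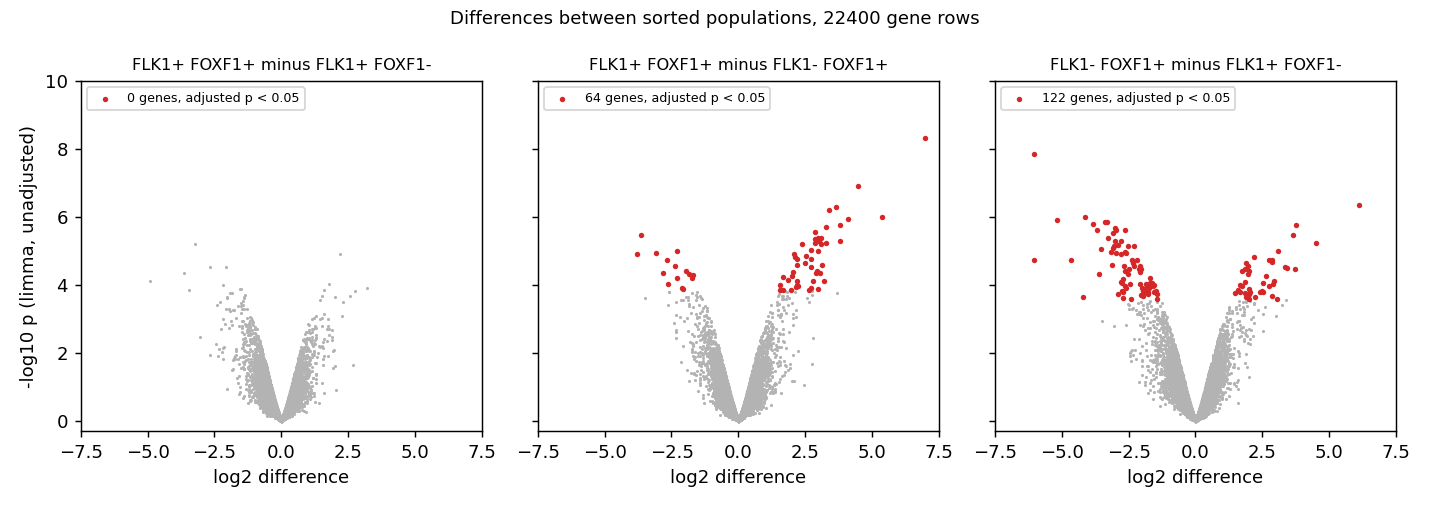
Log2 difference (horizontal) against -log10 of the unadjusted limma p (vertical) for each of 22400 genes in the 3 comparisons, with genes at an adjusted p under 0.05 in red. The panels hold 0, 64 and 122 such genes from left to right.

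The comparison of FLK1-negative FOXF1-positive with FLK1-positive FOXF1-negative cells sets the populations positive for only 1 of the markers against each other, and it gave the most genes. Of 122 genes past the threshold, 42 were higher and 80 lower in FLK1-negative FOXF1-positive cells. Their median differences were 2.31 log2 units (range 1.48 to 6.11) and -2.52 (range -6.05 to -1.44). ENSMUSG00000035783 was higher, at 11.37 ± 0.11 (SD, n = 2) against 5.26 ± 0.77, a difference of 6.11 ± 0.36 log2 units (SE, adjusted p = 0.00443). ENSMUSG00000043342 was higher at 11.16 ± 0.15 against 6.67 ± 0.21 (adjusted p = 0.00718). ENSMUSG00000041378 was lower, at 3.58 ± 0.02 against 9.63 ± 0.13 (adjusted p = 0.000304), and ENSMUSG00000070803 was lower at 5.33 ± 1.00 against 11.36 ± 0.29 (adjusted p = 0.0114). At an unadjusted p under 0.05 there were 1631 genes, or 7.28%. These counts also fell when any 1 array was left out, again more for an array of the populations compared. The loss of residual degrees of freedom lowers the counts here too, so the fall does not show whether particular arrays carried the calls. Without FLK1-positive FOXF1-negative sort 2 or FLK1-negative FOXF1-positive sort 2, the adjusted p of ENSMUSG00000043342 was 0.0589 or 0.0557. That of ENSMUSG00000070803 was 0.0694 without FLK1-positive FOXF1-negative sort 1, 0.0886 without its sort 2 and 0.0575 without FLK1-negative FOXF1-positive sort 1.

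**Figure D3:**
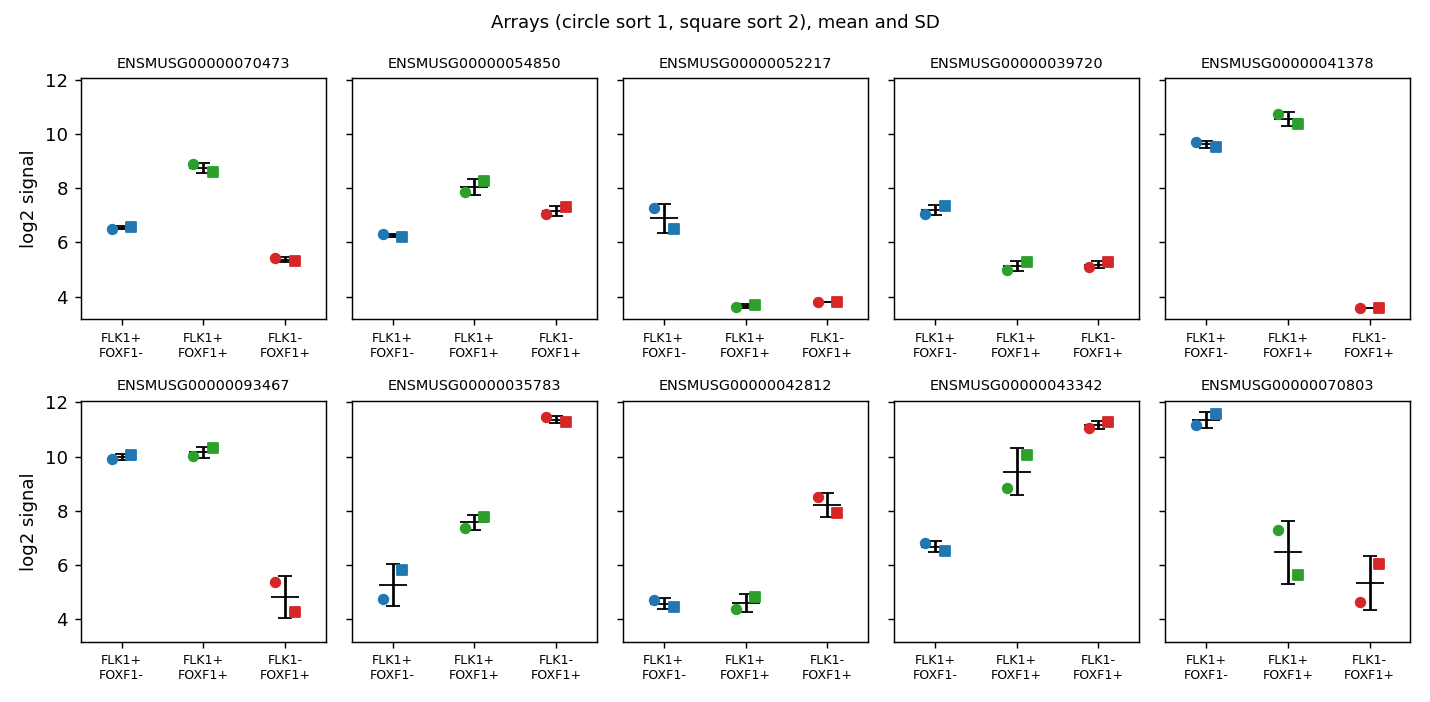
Log2 signal of the 10 gene IDs given in the text on each array, with circles for sort 1, squares for sort 2, and the mean with its SD (n = 2). ENSMUSG00000041378 lies at 9.63 and 10.55 in the FLK1-positive populations and at 3.58 in FLK1-negative FOXF1-positive cells, while ENSMUSG00000035783 steps from 5.26 over 7.57 to 11.37.

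Among the 122 genes that separated FLK1-negative FOXF1-positive from FLK1-positive FOXF1-negative cells, the double-positive cells lay mostly nearer to the FLK1-positive FOXF1-negative level. Of the 42 genes higher in FLK1-negative FOXF1-positive cells, the double-positive mean was nearer to the FLK1-positive FOXF1-negative mean for 33, or 78.6% (exact Clopper-Pearson 95% interval 63.2% to 89.7%). Of the 80 genes lower there, this held for 54, or 67.5% (56.1% to 77.6%). The remaining 26 included ENSMUSG00000070803, at 6.46 ± 1.17 (SD, n = 2) in double-positive cells. ENSMUSG00000035783, at 7.57 ± 0.28, was nearer to the FLK1-positive FOXF1-negative level, and ENSMUSG00000043342, at 9.44 ± 0.86, nearer to the FLK1-negative FOXF1-positive level. The double-positive mean lay beyond the FLK1-positive FOXF1-negative mean for 7 of the 42 genes and 26 of the 80. It lay beyond the FLK1-negative FOXF1-positive mean for 0 of the 42 and 3 of the 80. The intervals treat genes as independent, which they are not, and are therefore too narrow. Among the genes called higher without FLK1-positive FOXF1-negative sort 1 the share was 55.6%, and without its sort 2 it was 50%. Those lists were far shorter than the 42 genes and only partly drawn from them. These shares therefore do not show whether the position depends on an array.

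**Figure D4:**
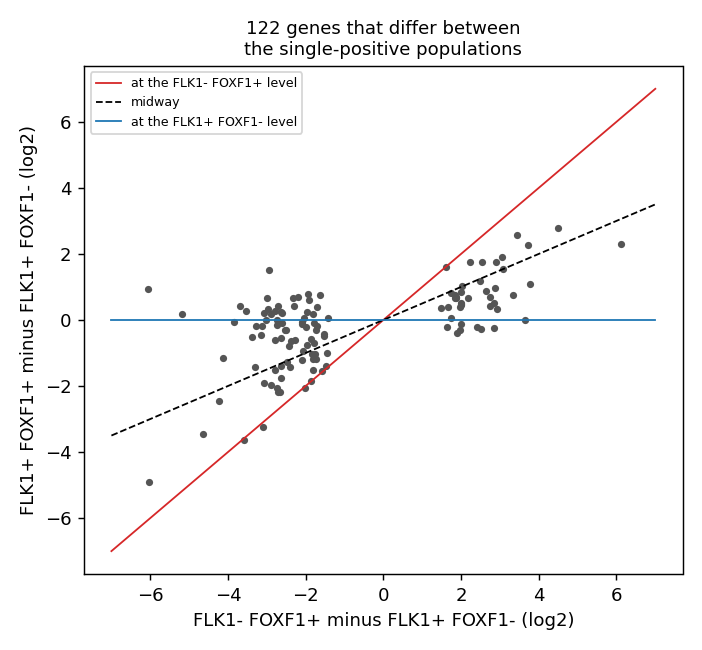
Difference of double-positive from FLK1-positive FOXF1-negative cells (vertical, log2) against that of FLK1-negative FOXF1-positive from FLK1-positive FOXF1-negative cells (horizontal, log2), 1 point for each of the 122 genes past the threshold in the latter comparison. Points between the blue and dashed lines are nearer to the FLK1-positive FOXF1-negative level, as are 33 of the 42 genes on the right and 54 of the 80 on the left when those beyond the blue line are included.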

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

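In double-positive against FLK1-positive FOXF1-negative cells, the gene-level count stayed at 0 in both directions under every alternative run, with a smallest adjusted p between 0.0698 and 0.611. Exon-level probe sets tested without grouping, added after the data were seen, gave 1 lower probe set. In double-positive against FLK1-negative FOXF1-positive cells they gave 160 higher and 45 lower, and in FLK1-negative FOXF1-positive against FLK1-positive FOXF1-negative cells 149 and 296, from 128950 rows, several of which can belong to 1 gene. Fitting only the populations compared left fewer residual degrees of freedom and gave 32 and 9 genes in the former comparison and 23 and 46 in the latter. Without gene rows equal to a single probe set, also added later, the genes lower in double-positive than in FLK1-negative FOXF1-positive cells numbered 23, and the cause was not tested. Leaving out 1 array at a time gave 2 to 32 higher and 0 to 9 lower genes in double-positive against FLK1-negative FOXF1-positive cells, and 6 to 23 and 20 to 46 in FLK1-negative FOXF1-positive against FLK1-positive FOXF1-negative cells. The lone array left in a population was then assumed to vary like the others. The share of genes for which double-positive cells were nearer to FLK1-positive FOXF1-negative cells ranged over these fits from 50% to 88.9% among the higher genes and from 62.9% to 100% among the lower. These fits called fewer genes, so their shares rest on fewer. The share was 77.8% among the lower genes when the dimmer 50% of rows was left out, and the cause was not tested. The other alternatives kept these counts within 1.5 times their value. Every call already exceeded 1 log2 unit, so requiring that could change nothing. Array weights, equal within populations, could not discount an array. No called gene changed sign, but none had overlapping arrays, so this tests little. Of 8 results past the threshold for single gene IDs, 5 lost the call when some array was left out, with adjusted p up to 0.158, and none did under the other 5 alternatives run for them. With the sort number as a replicate block the counts were 0 and 0, 42 and 14, and 40 and 67. The differences between sorts correlated across genes at 0.137, 0.0975 and 0.0591 between pairs of populations. These were not all over 0.1, so by the rule set beforehand the sorts were not taken as paired. An effect shared by sort number is not excluded: the second principal component had sort 1 above sort 2 in all 3 populations. With the block, 1272, 1557 and 1884 genes had an unadjusted limma p under 0.05, against 1047, 1313 and 1631 without it. For lack of gene names, the test of rows with exactly 1 symbol, the averaging of probe sets and all gene list tests were not run. The number of arrays limits these counts.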

Other observations

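The tests of spread, private genes, shared genes, covariance, single probe sets and mixing were devised after the main calls had been seen, and those of spread and of mixing in 1 share were chosen after values that bear on them had been seen. The genes called in FLK1-negative FOXF1-positive cells against each FLK1-positive population overlapped. Of the genes lower in them, 38 were called against both FLK1-positive populations, out of 49 and 80, where independent lists would share 0.175. Of the genes higher in them, 12 were called against both, out of 15 and 42, where independent lists would share 0.0281. In 100 simulations without any effect, the top-ranked lists of these sizes shared 11.7 genes on average (at most 19) and 3.95 (at most 8). There too the comparisons share arrays and the pooled spread of each gene, and the simulations do not separate the 2. Both comparisons use the same 2 FLK1-negative FOXF1-positive arrays, which are too few to split, so part of the overlap can come from the shared arrays. ENSMUSG00000041378 and ENSMUSG00000093467 were lower and ENSMUSG00000035783 and ENSMUSG00000042812 higher in FLK1-negative FOXF1-positive cells in both comparisons.

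Some of the genes with the smallest p between the FLK1-positive populations differed past the threshold elsewhere. ENSMUSG00000052217 and ENSMUSG00000039720 were lower in FLK1-negative FOXF1-positive than in FLK1-positive FOXF1-negative cells by limma (adjusted p = 0.00812 and 0.0147). The same FLK1-positive FOXF1-negative arrays enter both comparisons, so these calls are not independent of how the genes were picked. ENSMUSG00000070473 was higher in double-positive than in FLK1-negative FOXF1-positive cells by 3.38 ± 0.21 log2 units (SE, adjusted p = 0.00352), with the same double-positive arrays in both comparisons.

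No gene passed the threshold between the FLK1-positive populations, against 64 and 122 in the other comparisons. The ratio of the median SD between their sorts to that of the FLK1-negative FOXF1-positive cells was 0.998. It does not bear on these counts, because the fit pools the spread, with a median standard error of 0.251 log2 units in all 3 comparisons. After quantile normalization again or median centring, 0 genes passed too. The array medians already lay between 6.00 and 6.07, so these steps shifted the arrays little and do not decide whether scaling played a part. A smaller difference between these populations is a candidate explanation: the covariance across genes of differences taken from separate arrays was 0.00845 on average, against 0.0386 and 0.0747 in the other comparisons, and lowest in both ways of matching the arrays. That average hides 0.0241 for arrays of the same sort number and -0.00717 for the crossed matching, against 0.0455 and 0.0318 and against 0.0861 and 0.0634, so same-numbered arrays gave more in all 3 comparisons. An effect shared by sort number would cancel in the same-numbered matching but lower the crossed one. The average can therefore understate the difference between the populations, while the same-numbered value was still the lowest of the 3 comparisons. A difference in a few genes stays open: 54 genes had an unadjusted p under 0.001, where chance gives 22.4.

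The double-positive arrays lay between the other populations on the first principal component. A mixture of the cells of the other 2 populations could give this, and predicts few genes outside their range: 9 genes had both double-positive arrays at least 1 log2 unit outside the other 4, against 43 for the FLK1-positive FOXF1-negative and 125 for the FLK1-negative FOXF1-positive arrays, and mismatched pairs of arrays reached up to 12. That count, no higher than 12, leaves a mixture possible. The highest mismatched pairs, at 12 and 11, were both of sort 2 arrays. Mismatched pairs of unlike sort number reached up to 9, which the double-positive count equalled but did not exceed. A mixture with 1 share for all genes of an array is argued against as the whole cause. The simulated mixtures had no sampling of 50 cells and no amplification, which could also move genes off 1 share, so a mixture of unlike cells stays open. Of the 122 genes called between the other populations, at least 45 (36.9%) departed from the mixture by limma's spread whatever the shares. At most 4 (3.92%) did in 80 simulated mixtures, whose own lists held 86 to 115 called genes. The number was 48 with mixing on the log2 scale, 26 without FLK1-positive FOXF1-negative sort 1, 23 without double-positive sort 1, 24 without its sort 2, and 32 to 42 without each of the others, against at most 3 in the simulated mixtures with an array left out. An intermediate state stays open and untested, as do gates that held other cells, since the sorting genes were not identified here. The log2 signal of ENSMUSG00000042812 was 4.58 in double-positive, 4.57 in FLK1-positive FOXF1-negative and 8.21 in FLK1-negative FOXF1-positive cells. If this gene is Foxf1, that goes against the double-positive label, although RNA is there set against a gate on the VENUS protein.

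Gene rows that rest on a single probe set could be noisier and so fill the lists of called genes. They made up 21 of the 136 genes called in any comparison, or 0.537 times their share among all rows, so they did not fill the lists. They were noisier, with a median residual SD of 0.267 against 0.239 log2 units in other rows. A larger spread itself lowers the number of calls, so a low share, taken beforehand as evidence against noise, does not decide whether the calls among them come from it.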
